A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

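RNA from budding yeast cells carrying a doxycycline-repressible tetO7 promoter before the coding region of YPI1 was measured on 2-colour microarrays. Treated and untreated cells were compared after 2, 4 and 6 h, with 2 dye-swapped arrays per time, which gives 6 arrays from 6 RNA samples. Total RNA was copied into oligo-dT primed cDNA, per the labels' protocols. The authors dropped spots under 120 µm in diameter or under 100 units of Cy3 and Cy5, per the description in the labels, and these appear as empty cells.

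The deposited values are log2 ratios, 1 per open reading frame and array, as far as the values show. The log base is not stated in the labels. The range excludes log10 in practice, natural logs were not excluded, and every fold given here assumes log2. The ratio was taken as doxycycline over untreated on every array, because the labels put treated RNA in the first channel and YPI1 was strongly negative on all 6 arrays. The method of normalization, the averaging of spots and the turning of the swapped arrays were not given in the sources used here. One array of 2 h has the same dye in the labels for both channels and was taken as the dye swap. Doxycycline was in Cy5 on replicate 1 of 2 h, replicate 1 of 4 h and replicate 2 of 6 h, and in Cy3 on the others.

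A rule written before the data were examined asked for a sign turn of the Cy3 arrays at any time whose swapped arrays correlated below 0. Across genes, which are not independent replicates, the swapped arrays correlated with r = −0.40 at 2 h, −0.17 at 4 h and 0.87 at 6 h. The turn was not made, because it would leave YPI1 at 0.34 at 2 h and 0.16 at 4 h. It was run as an alternative instead. Arrays of like dye orientation did not all run the same way either, since replicate 1 of 4 h and replicate 2 of 6 h correlated with r = −0.25, or −0.31 without YPI1.

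Of 6212 identifiers, 5662 matched a gene of the R64 reference annotation by systematic name, 24 of them after a change to upper case. The other 550 kept their identifiers. Arrays held values for 4250 to 4804 genes. In total 5305 genes had a value on at least 1 array, 3391 on all 6, and 907 on none. Signal intensities were not analysed here, so the depth of each value is unknown and the number of arrays limits the precision. Gene lengths are annotated spans, introns included, and the chromosome was read from the systematic name.

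The 2 arrays of a time share their RNA and were averaged first. The SD given beside a value of 1 time is over these 2 arrays and is technical. With 1 RNA pair per time, no p was computed for a single time. A gene was counted there if its log2 ratio was at least 1 in size, a 2-fold change, with 1 sign on both arrays, and the number with opposite signs is given beside it. Over the times, with n = 3 RNA pairs, limma 3.58.1 in R 4.3.3 (lmFit and eBayes) tested the mean of the 3 time values against 0, and the slope through 0 on hours. Both tests were two-sided with Benjamini-Hochberg adjustment at 0.05 over the 3391 genes. The 3 pairs differ in hours of doxycycline, so change over time counts as error in the test of the mean. No p over the times, of genes or of lists, measures the spread between biological replicates.

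In total 33 gene lists were fixed before the data were examined. Camera, with a preset correlation of 0.01 between genes, tested the 32 lists with at least 5 measured members on the mean over the times. The list of the neighbours of YPI1 has 2 members and was given as single genes. At each time the median of a list was placed among 10000 random lists of its size, as a description with no p. These percentiles could not be matched on signal, which was not analysed here.

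Because the 6 h ratios went with gene length and chromosome, 2 corrections were added after the values were seen. The first took from each array its lowess curve on log2 gene length, with a span of 0.3 and 3 robust steps. The second took from each gene the median of the 20 genes nearest in length on the same chromosome, called matched genes here. The difference from matched genes, computed on each array and averaged, is given beside the 6 h values of lists and of the genes named for 6 h, where a gene had one. Further alternatives were median centring, scaling of the arrays, other filters, fold limits and variance models, arrays as units, left-out arrays and times, the dye as a term, and other set tests.

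Genes were named by a rule fixed before the data were examined. It took the 12 highest and 12 lowest means over the times, first among genes past the test and then among genes of 1 sign on all 6 arrays. It took the 8 highest and 8 lowest genes past the 2-fold rule at each time, and up to 4 members of each list by size of the mean. YPI1, NIC96, RPN11, GLC7, SDS22 and ENA1 were named whatever their values. PHO11, VTC3, BOP2, RTS2, YOL106W, YFR035C and RSC8 were named after their values were seen.

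The steps were tested on simulated data of 3391 genes with 200 changed. The test of the mean recovered 0, 161 and 196 of them at log2 changes of 1, 2 and 4, and the slope test 0, 114 and 194 at changes of 1, 2 and 4 at 6 h. False calls were 0, 4 and 13 for the mean and 0, 6 and 7 for the slope. On 5662 simulated genes the matched-gene correction recovered 199 of 200 changed genes with 8 false calls. The simulated difference between chromosomes was placed on X to XIII, where the data showed one. Its noise was below the real 6 h spread, for which genes of 2000 to 2300 bp had SDs of 0.50 and 0.76 by chromosome group. That simulation therefore does not give the error of the 6 h counts. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No array was left out.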

Results

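The cells were budding yeast in which YPI1 stands behind a tetO7 promoter, which doxycycline shuts off. YPI1 encodes a regulatory subunit of Glc7, the catalytic subunit of protein phosphatase 1, and the title of the series asks about its role in progression through mitosis. Cells grown in YPD, a rich glucose medium, were compared with and without 100 µg/ml doxycycline after 2, 4 and 6 h. The arrays held log2 ratios of treated over untreated cells for 4686 and 4287 genes at 2 h, 4804 and 4800 at 4 h, and 4723 and 4250 at 6 h. Each time had 1 RNA pair on 2 dye-swapped arrays, so values at a time are mean ± SD of 2 technical arrays, with no biological replicate. No strain with an unmodified YPI1 promoter was among the samples, so any effect of doxycycline itself is part of every ratio. Untreated cells also carried the tetO7 promoter, so no ratio of YPI1 is against its native level.

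YPI1 (YFR003C), the gene under the promoter, fell on all 6 arrays, the earliest included. Its log2 ratio was −4.39 ± 0.48 at 2 h, −5.48 ± 0.23 at 4 h and −6.30 ± 0.19 at 6 h, which is 21.0, 44.6 and 79.0 times below untreated cells. Over the times the mean was −5.39 (limma adjusted p = 0.0104, lower on 6 of 6 arrays), and YPI1 passed the slope test (limma adjusted p = 0.0174) with −1.22 per hour on a line forced through 0 at the start, which is steeper than the change between the measured times. Relative to matched genes, the 20 nearest in length on the same chromosome, the mean was −5.24 with a limma adjusted p = 0.0961 and the slope −1.18 with an adjusted p = 0.348, and the 6 h value was −5.87.

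**Figure D1:**
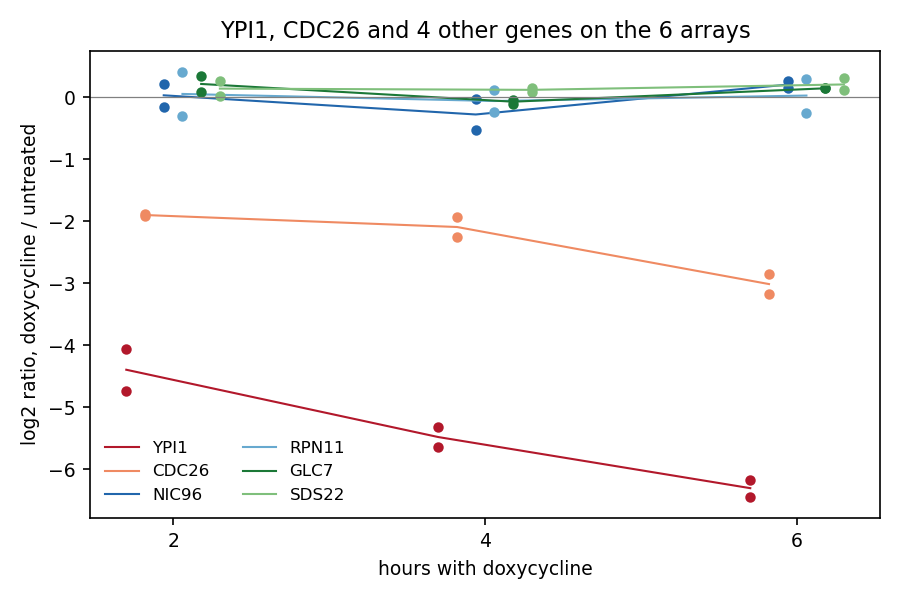
Log2 ratio of treated over untreated cells (vertical axis) against hours of doxycycline (horizontal axis), with points for single arrays, set slightly apart by gene, and lines through the means of 2 arrays. YPI1 ran from −4.39 to −6.30 and CDC26 from −1.90 to −3.01, while the means of NIC96, RPN11, GLC7 and SDS22 lay between −0.28 and 0.21.

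CDC26 (YFR036W), a subunit of the anaphase-promoting complex, which marks mitotic proteins for destruction, was the gene with the next lowest mean over the times. Its log2 ratio was −1.90 ± 0.02 at 2 h, −2.09 ± 0.22 at 4 h and −3.01 ± 0.22 at 6 h, or 3.73, 4.27 and 8.08 times below untreated cells. CDC26 passed the slope test with −0.54 per hour on a line forced through 0 at the start (limma adjusted p = 0.0174, lower on 6 of 6 arrays), while its mean of −2.34 did not pass (limma adjusted p = 0.125). With the length curve removed the mean of CDC26 was −2.08 and passed (limma adjusted p = 0.037) while the slope of −0.46 did not (adjusted p = 0.319). The mean also passed with arrays scaled, with any 1 time left out and with 6 arrays as units, which counts dye swaps as replicates, and did not with arrays centred, a looser filter, a robust variance or either replicate left out. Against matched genes it did not pass, with a mean of −2.19 (limma adjusted p = 0.126) and a slope of −0.49 (adjusted p = 0.348), and its 6 h value was −2.58. CDC26 lies on the same chromosome arm as YPI1 with 37 annotated genes between them.

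The genes on either side of YPI1 had no ratio near that of YPI1. NIC96, a nuclear pore subunit, had log2 ratios of 0.03 ± 0.26, −0.28 ± 0.35 and 0.20 ± 0.09 at 2, 4 and 6 h, and RPN11, a proteasome lid protease, had 0.05 ± 0.50, −0.06 ± 0.26 and 0.02 ± 0.39. GLC7 itself had 0.21 ± 0.19, −0.07 ± 0.05 and 0.14 ± 0.00. SDS22, another regulator of Glc7, had 0.14 ± 0.17, 0.12 ± 0.04 and 0.20 ± 0.14. Against matched genes the 6 h values turned to −0.62 for NIC96, −0.04 for RPN11 and −0.55 for GLC7, and SDS22 had 0.14. ENA1, a sodium pump, had no value. Among 11 tested Glc7 regulators and relatives, 1 passed the test of the mean, YPI1, over all genes and also when adjusted over the list alone. Their median over the times was 0.15 and their mean −0.32, which YPI1 turns below 0 (camera adjusted p = 0.610, direction up).

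Over the 3 times together, and only at the preset correlation, ribosomal protein and meiosis genes stood apart on the low side. Some carbohydrate, cell-cycle, cell wall, ergosterol and stress lists did so on the high side. Among cell-cycle lists the MCM cluster (camera adjusted p = 0.123), spindle and anaphase genes (0.61) and histones (0.393, direction down) did not pass. Camera placed 11 of 32 lists past its threshold, 9 up and 2 down. The 108 tested ribosomal protein genes were down (adjusted p = 2.41e-16) with a median mean of −0.36. The 9 genes of glycogen and trehalose metabolism, the reserve carbohydrates of yeast, were up (adjusted p = 0.000102, median mean 0.38), and so were 30 G1/S genes, which start DNA replication (adjusted p = 0.00056, median mean 0.25). The other lists up were the CLB2 cluster of G2/M genes (adjusted p = 0.00211), ergosterol synthesis (0.0166), the Msn2/4 stress response (0.0166), glycolysis (0.0224), glucose-repressed genes (0.0228), cell wall integrity targets (0.0241) and the SIC1 cluster of M/G1 genes (0.0443), and meiosis and sporulation was down (0.0345). None of the 32 lists passed with an estimated correlation, the lowest being adjusted p = 0.662 with an estimated correlation. In the list tests YPI1 was the 1 gene past the test of the mean in any list, both over all genes and adjusted over the list alone.

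Most of these list calls depended on 1 time or on replicate 1. With 6 h left out, 3 of the 11 lists passed in the same direction, the Msn2/4 stress response (camera adjusted p = 0.000458), the CLB2 cluster (0.0346) and glycogen and trehalose (0.0478). Ribosomal proteins (0.208), ergosterol synthesis (0.975), glycolysis (0.878) and meiosis (0.71) then turned direction without passing. With replicate 1 of each time left out, 4 of the 11 passed, ribosomal proteins (camera adjusted p = 3.21e-22), glycogen (0.000334), G1/S (0.000334) and CLB2 (0.00602). The stress response (0.163), meiosis (0.166), cell wall (0.198), glucose-repressed genes (0.198), ergosterol (0.224), the SIC1 cluster (0.224) and glycolysis (0.521) did not. With 4 h left out the stress response (0.121), cell wall (0.076), glucose-repressed genes (0.0907) and the SIC1 cluster (0.0907) did not pass, nor did ergosterol (0.0686) with 2 h left out. Relative to matched genes 7 of the 11 passed, ribosomal proteins (camera adjusted p = 1.36e-11), the stress response (7.75e-08), glycogen (0.00496), cell wall (0.00496), G1/S (0.0051), glycolysis (0.0335) and CLB2 (0.0492). Ergosterol (0.109), glucose-repressed genes (0.108), meiosis (0.163) and the SIC1 cluster (0.392) did not. An estimated correlation was not run on the values relative to matched genes or with arrays or times left out.

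Beyond YPI1, no single gene passed the limma test of the mean, of 3391 tested, and 10 had an unadjusted p below 0.05, YPI1 among them. The genes lowest in mean with 1 sign on all 6 arrays included VTC1, of the polyphosphate polymerase (−0.66), PAU11, a seripauperin (−0.63), SNZ1, of vitamin B6 synthesis (−0.54), NCE103, carbonic anhydrase (−0.53), and PHO12, a secreted acid phosphatase (−0.48). SUT2, FMP23, GON7, YHI9 and POP5 lay between −0.53 and −0.42. The highest included WSC4, a cell wall sensor family member (0.76), HXK1, hexokinase (0.75), PDR12, a weak-acid pump (0.68), PGM2, phosphoglucomutase (0.60), ADE17, of purine synthesis (0.58), and UGP1, which makes UDP-glucose (0.54). CAF120, IXR1, HSP30, DCW1, CYT1 and HSP26 lay between 0.57 and 0.33. For all of these the limma adjusted p was 0.806. The slope test called YPI1 and CDC26 and no others, with 486 genes at an unadjusted p below 0.05. It called 1768 genes with 4 h left out, 760 higher and 1008 lower, and 11 with 6 h left out. With the 6 h arrays left out the limma test of the mean called 11 genes, 2 higher and 9 lower.

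At 2 h the cells differed from untreated cells in YPI1 and CDC26 and in little else by size. These 2 of 4119 genes passed the 2-fold rule, both lower, while 2 passed it with opposite signs on the swapped arrays, YOL106W at −1.32 and 1.07 and RTS2 at 1.57 and −1.84. Phosphate (PHO) regulon genes, which take up and store phosphate, had a median log2 ratio of −0.11 (array medians −0.08 and −0.27) over 17 measured members, at percentile 0.26 of random lists, with 7 below 0 on both arrays. PHO12 was at −0.57 ± 0.29 and VTC1 at −0.34 ± 0.30, while VTC2 and VTC5 of the same list were at 0.26 ± 0.36 and 0.09 ± 0.24. Glycogen and trehalose genes had a median of 0.14 (0.27 and 0.08; 14 members, percentile 99.9), with GLC3, the branching enzyme, at 0.38 ± 0.19. Stress response genes had a median of 0.08 (0.15 and −0.04; 38 members, percentile 99.9), with HSP26 at 0.24 ± 0.09. The CLB2 cluster had 0.07 (0.07 and 0.08; 29 members, percentile 99.4) and G1/S genes 0.07 (−0.04 and 0.10; 38 members, percentile 99.8). Ribosomal protein genes had −0.07 (118 members, percentile 0), with array medians of opposite sign, 0.09 and −0.23.

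For most genes at 2 h the swapped arrays differed by more than they shared. The SD of their mean over genes was 0.165 and that of the deviation of either array from the mean 0.25. Of 32 lists, 2 lay in the lowest and 5 in the highest 2.5% of random lists, against 6 and 1 without replicate 1 and 2 and 9 without replicate 2. The 2 h mean had a Spearman correlation of 0.15 with gene length (−0.06 and 0.28 on the arrays). These random lists were not matched on length. Among random lists matched on length the 2 h counts were 4 and 5, and relative to matched genes 5 and 3.

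At 4 h the genes past 2-fold were YPI1, CDC26 and PHO84 (YML123C), the main high-affinity phosphate transporter. These 3 of 4691 genes were all lower, and 1 gene, RTS2, passed with opposite signs at 1.87 and −1.72. PHO84 was at −1.98 ± 0.08, had no pair of values at 2 h, and was at −0.80 ± 0.08 at 6 h (−1.42 relative to matched genes). The PHO regulon as a list had a median of −0.15 (array medians −0.10 and −0.23; 19 members, percentile 0), with 10 members below 0 on both arrays, PHO12 at −0.68 ± 0.40 among them. Amino acid biosynthesis genes had a median of −0.14 (−0.04 and −0.20; 47 members, percentile 0), with 20 below 0 on both arrays and none above, TRP5 of tryptophan synthesis at −0.32 ± 0.08. The stress response list was on the high side at 0.10 (0.18 and 0.06; 42 members, percentile 100), with 24 members above 0 on both arrays and 2 below, HSP26 at 0.32 ± 0.10. Heat shock genes lay at −0.09 (−0.15 and 0.02; 26 members, percentile 0.11), STI1, a chaperone partner, at −0.33 ± 0.05. Ribosomal protein genes had 0.12 (130 members, percentile 100), again with array medians of opposite sign, 0.32 and −0.10. The 4 h mean was lower for longer genes, with a Spearman correlation of −0.29 with gene length (−0.43 and 0.19 on the arrays). Median ratios ran from 0.073 for genes up to 522 bp to −0.07 for genes of 1533 to 1899 bp. That is near the size of these list medians, and the random lists were not matched on length.

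At 4 h the SD of the mean over genes was 0.16 and that of the deviation of either array 0.19, and of 32 lists 6 lay in the lowest and 4 in the highest 2.5% of random lists, against 8 and 3 without replicate 1 and 2 and 5 without replicate 2. The 4 h counts were 5 and 5 among random lists matched on length, and 4 and 6 relative to matched genes. Across genes the means of 2 h and 4 h correlated with r = −0.12 without YPI1.

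**Figure D2:**
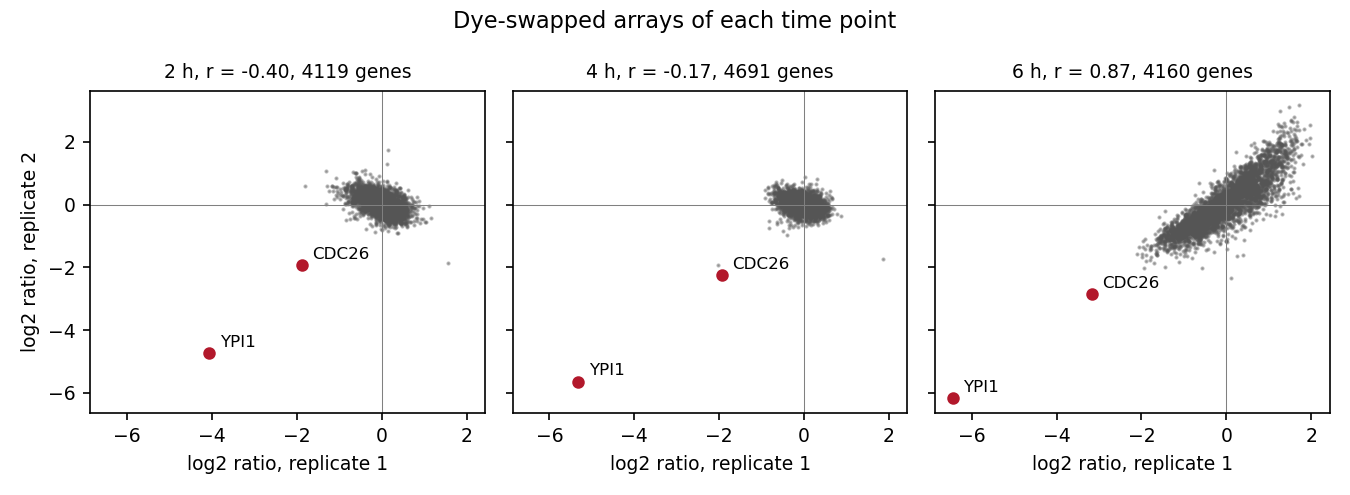
Log2 ratio of treated over untreated cells on replicate 1 (horizontal axis) against replicate 2 (vertical axis), 1 point per gene, for 2, 4 and 6 h. The swapped arrays correlated with r = −0.40 at 2 h, −0.17 at 4 h and 0.87 at 6 h, with YPI1 low on both arrays each time.

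At 6 h a broad difference appeared, with ribosomal protein genes far below untreated cells and the medians of many lists above. The reserve carbohydrate, G1/S, cell wall and heat shock lists were above 0, as were many others. Of 32 lists, 16 lay in the highest 2.5% of random lists. Of 4160 genes, 459 passed the 2-fold rule, 267 higher and 192 lower, with none of opposite sign. After each array was centred on its own median, 0.013 for replicate 1 and −0.104 for replicate 2, the counts were 272 higher and 120 lower. The balance turned to 46 higher and 187 lower with the length curve removed, and to 635 higher and 919 lower at 1.5-fold. The SD of the mean over genes was 0.756 against 0.2 for the deviation of either array, so the 6 h RNA pair gave nearly the same profile in both dye orientations. The ratios were also higher for longer genes, with a Spearman correlation of 0.63 with gene length in the annotation across genes, which are not independent replicates, and they differed between chromosomes at like length. Genes of 2000 to 2300 bp had a median of −0.52 (SD 0.50, 111 genes) on chromosomes X to XIII and 1.14 (SD 0.76, 85 genes) on the other 12, a split chosen after the values were seen. Nor did the rise hold at all lengths. The median was 1.33 (SD 0.58, 29 genes) for genes of 2850 to under 3000 bp. It was 0.41 (SD 0.33, 29 genes) from 3003 to under 3150 bp, a limit also chosen after the values were seen. Set against matched genes, 135 of 3921 genes passed the rule, 57 higher and 78 lower, of which 25 were among the 259 higher and 24 among the 169 lower genes of the uncorrected count that have a length. For single genes at 6 h, the log2 ratio relative to matched genes follows in parentheses.

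**Figure D3:**
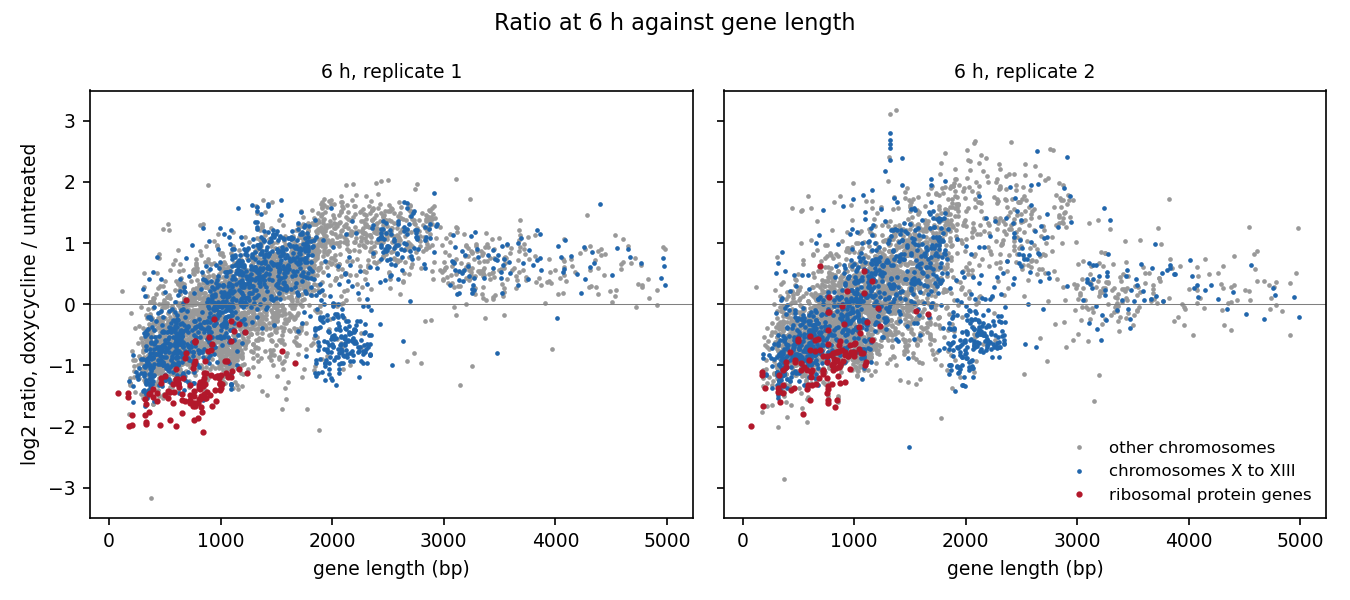
Log2 ratio at 6 h (vertical axis) against gene length in bp up to 5000 (horizontal axis), 1 point per gene and 1 panel per array, with genes of chromosomes X to XIII in blue, those of other chromosomes in grey and ribosomal protein genes in red. YPI1 lies below the axis and is left out, and genes of 2000 to 2300 bp had medians of −0.52 on chromosomes X to XIII and 1.14 elsewhere.

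Ribosomal protein genes were the lowest list at 6 h. Their median log2 ratio was −1.14 (array medians −1.36 and −0.93), 114 of 120 measured members were below 0 on both arrays, and 49 passed 2-fold lower and none higher. RPL39 was at −1.84 ± 0.07 (−1.31), RPL25 at −1.83 ± 0.37 (−1.48), RPL29 at −1.83 ± 0.22 (−1.39), RPS30B at −1.78 ± 0.31 (−1.08) and RPL42B at −1.74 ± 0.20 (−1.40). Relative to matched genes the median was −0.70, and 10 of the 78 genes past 2-fold lower were ribosomal protein genes. Ribosome biogenesis genes, which build the ribosome, differed from them, with a median of 0.18 (90 members, 6 higher and 1 lower past 2-fold) and −0.08 relative to matched genes. NOP12, of this list, had one of the highest ratios at 2.44 ± 1.04 (2.02), with a wide spread between its arrays.

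Reserve carbohydrate, glucose-repressed and glycolysis genes had medians above 0 at 6 h, and TCA cycle genes a median below 0. Glycogen and trehalose genes had a median of 0.98 (0.84 and 1.10), 3 of 10 past 2-fold, and 0.33 relative to matched genes. PGM2 was at 1.34 ± 0.27 (0.66), UGP1 at 1.23 ± 0.11 (0.57), TSL1, of the trehalose synthase complex, at 1.14 ± 0.33 (0.48) and GLC3 at 1.55 ± 0.38 (0.10). Glucose-repressed genes had 0.51 (21 members, 2 higher and 1 lower past 2-fold) and 0.17 relative to matched genes, with HXK1 at 1.75 ± 0.11 (1.21). Glycolysis genes had 0.59 (0.19 and 0.97; 2 of 17 past 2-fold) and 0.28 relative to matched genes, where the arrays gave −0.06 and 0.63. PFK1 and PFK2, the phosphofructokinase subunits, were at 1.48 ± 0.31 (0.80) and 1.60 ± 0.42 (0.84). TCA cycle and respiratory genes had −0.53 (38 members, 3 higher past 2-fold) but 0.17 relative to matched genes, with the NADH dehydrogenase NDI1 at 1.62 ± 0.11 (1.13) and the ATP synthase subunit ATP16 at −0.90 ± 0.23 (−0.09).

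Of the cell-cycle lists, G1/S genes had the highest median at 6 h and histone genes the lowest. G1/S genes had a median of 0.74 (0.81 and 0.60), 5 of 34 past 2-fold higher and none lower, and 0.22 relative to matched genes. The G1 cyclins CLN2 and PCL1 were at 1.16 ± 0.30 (1.00) and 1.06 ± 0.35 (1.38). The MCM cluster had 0.68 (11 members) but 0.06 relative to matched genes, with MCM7, of the replicative helicase, at 1.63 ± 0.11 (0.28). The CLB2 cluster had 0.52 (0.23 and 0.56; 3 of 27 past 2-fold) and 0.08, with PMA1, the plasma membrane proton pump, at 2.25 ± 0.40 (0.97) and CHS2, the septum chitin synthase, at 1.23 ± 0.38 (0.26). ALK1, a haspin-like kinase of the CLB2 cluster, was at 1.20 ± 0.05 (−0.07), turning direction against matched genes. The SIC1 cluster had 0.46 (3 of 19 past 2-fold) and 0.13, with the daughter-cell genes CTS1, chitinase, at 1.59 ± 0.51 (0.84) and DSE2 at 1.26 ± 0.17 (1.25). Spindle and anaphase genes had 0.24 (17 members, 1 past 2-fold) and 0.11, with SLK19 at 1.56 ± 0.16 (0.26) and the Aurora kinase IPL1 at −0.76 ± 0.00 (−0.06). Histone genes had −0.61 (10 members, none past 2-fold) and 0.13 relative to matched genes, with HTZ1 at −0.80 ± 0.30 (0.02) and HHO1 at 0.55 ± 0.03 (0.90).

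Cell wall integrity targets had a median of 0.67 (0.56 and 0.83; 1 of 20 past 2-fold), and 0.56 relative to matched genes. SED1, a major wall glycoprotein, was at 0.90 ± 0.15 (1.78), PIR3, another wall protein, at 1.07 ± 0.22 (1.10), and RLM1, the transcription factor of the pathway, at 1.61 ± 0.43 (0.56). Calcineurin targets had 0.50 (25 members, 2 past 2-fold) and 0.16 relative to matched genes, with the Golgi calcium pump PMR1 at 1.45 ± 0.36 (0.18). Genes of the Glc7 regulator list had 0.55 (15 members, 2 higher and 1 lower, YPI1) and 0.10, with SCD5 at 1.92 ± 0.47 (0.86), PPZ2 at 1.32 ± 0.48 (0.46) and BNI4 at 1.07 ± 0.08 (0.26).

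Stress lists were mixed at 6 h. Heat shock genes had a median of 0.52 (24 members, 9 higher and 2 lower past 2-fold) and 0.27 relative to matched genes, with the chaperones SSA4 at 1.62 ± 0.13 (0.30) and HSP104 at 1.48 ± 0.02 (0.77). The Msn2/4 stress response had 0.08 (39 members, 4 higher and 2 lower) and 0.37 relative to matched genes, with GAD1 at 1.25 ± 0.24 (0.56), HSP26 at 0.43 ± 0.02 (0.99) and HSP12 at −0.44 ± 0.08 (0.04). Unfolded protein response genes had 0.46 (3 of 19 past 2-fold) and 0.17, with the mannosyltransferases PMT1 and PMT2 at 1.62 ± 0.46 (0.55) and 1.64 ± 0.56 (0.73). The osmotic stress list had −0.20 (13 members) and 0.04, DNA damage genes 0.25 (12 members, 1 past 2-fold) and −0.01 with RAD52 at 0.85 ± 0.13 (0.39), and multidrug resistance genes 0.14 (21 members) and 0.04 with the thioredoxin TRX2 at −1.24 ± 0.31 (−0.50). Proteasome genes had −0.01 (2 of 32 past 2-fold) and 0.21, with CDC48, a protein-unfolding ATPase, at 1.55 ± 0.24 (0.53).

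Metabolic and nutrient lists spread over both sides at 6 h. Sulfur and methionine genes had a median of 0.76 (3 of 18 past 2-fold) and 0.23 relative to matched genes, with the ubiquitin ligase subunit MET30 at 1.26 ± 0.06 (0.31). Amino acid biosynthesis genes had 0.39 (5 of 45 past 2-fold) and 0.16, with LYS4 at 2.10 ± 0.80 (1.16) and TRP5 at 1.87 ± 0.62 (0.61). Nitrogen catabolite genes had 0.43 (14 members, 1 past 2-fold) and 0.09, with the transcription factor GLN3 at 1.85 ± 0.35 (0.45). Ergosterol genes had 0.45 (2 of 24 past 2-fold) and 0.15, with NCP1, a P450 reductase, at 2.15 ± 0.68 (0.97) and ERG13 at 1.13 ± 0.05 (0.63). Iron regulon genes had 0.32 (23 members, 2 higher and 1 lower) and 0.12, with the siderophore transporter ARN1 at 1.45 ± 0.68 (0.20). Zinc and copper genes had −0.14 (14 members, 1 higher and 2 lower) and −0.24, with FRE7, a metal reductase, at 1.53 ± 0.52 (0.47). ZPS1 and IZH2, of the same list, were lower, at −0.99 ± 0.17 (−0.64) and −0.77 ± 0.00 (−0.52). The PHO regulon had −0.13 (17 members, 2 higher and 1 lower) and −0.16, with VTC1 at −1.39 ± 0.35 (−0.90). VTC5 and VTC2, of the same list, were higher, at 1.13 ± 0.12 (0.09) and 1.09 ± 0.02 (0.32).

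Of the developmental and anaerobic lists, the meiosis list was low at 6 h also against matched genes. Meiosis and sporulation genes had a median of −0.83 (−0.95 and −0.75), all 10 measured members were below 0 on both arrays, 1 passed 2-fold, and the median was −0.55 relative to matched genes. SPS100, a spore wall gene, was at −1.07 ± 0.34 (−1.08) and the kinase SMK1 at −0.84 ± 0.23 (−0.55). Seripauperins and related wall proteins had −0.32 (18 members, 1 lower) but 0.30 relative to matched genes, with PAU23 at −1.21 ± 0.07 (−0.35). Pheromone response genes had 0.17 (19 members, 1 higher and 2 lower) and −0.01, with the agglutinin AGA1 at 2.05 ± 0.49 (0.94) and PRM3 at −1.47 ± 0.52 (−0.63).

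Outside these lists, the highest ratios at 6 h included DSS1, a mitochondrial exoribonuclease, at 2.12 ± 0.42 (1.35), and ADE57, of purine synthesis, at 2.11 ± 0.76 (0.86). YAR010C at 2.30 ± 1.15 (1.76) and YJR028W at 2.19 ± 0.85 (1.54) are Ty transposon reading frames with near-identical copies, so their identity is uncertain, and YFL032W, a reading frame with no symbol, was at 2.12 ± 1.21 (no matched value). Beyond YPI1, CDC26 and the ribosomal protein genes, the lowest among genes past 2-fold were YJL188C, a reading frame that overlaps RPL39 and so is uncertain, at −1.98 ± 0.05 (no matched value), and DAK2, dihydroxyacetone kinase, at −1.78 ± 0.10 (−2.44). Of 32 lists at 6 h, 3 lay in the lowest and 16 in the highest 2.5% of random lists, and 2 and 11 relative to matched genes. The counts were 4 and 10 without replicate 2, and 2 and 9 among random lists matched on length.

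**Figure D4:**
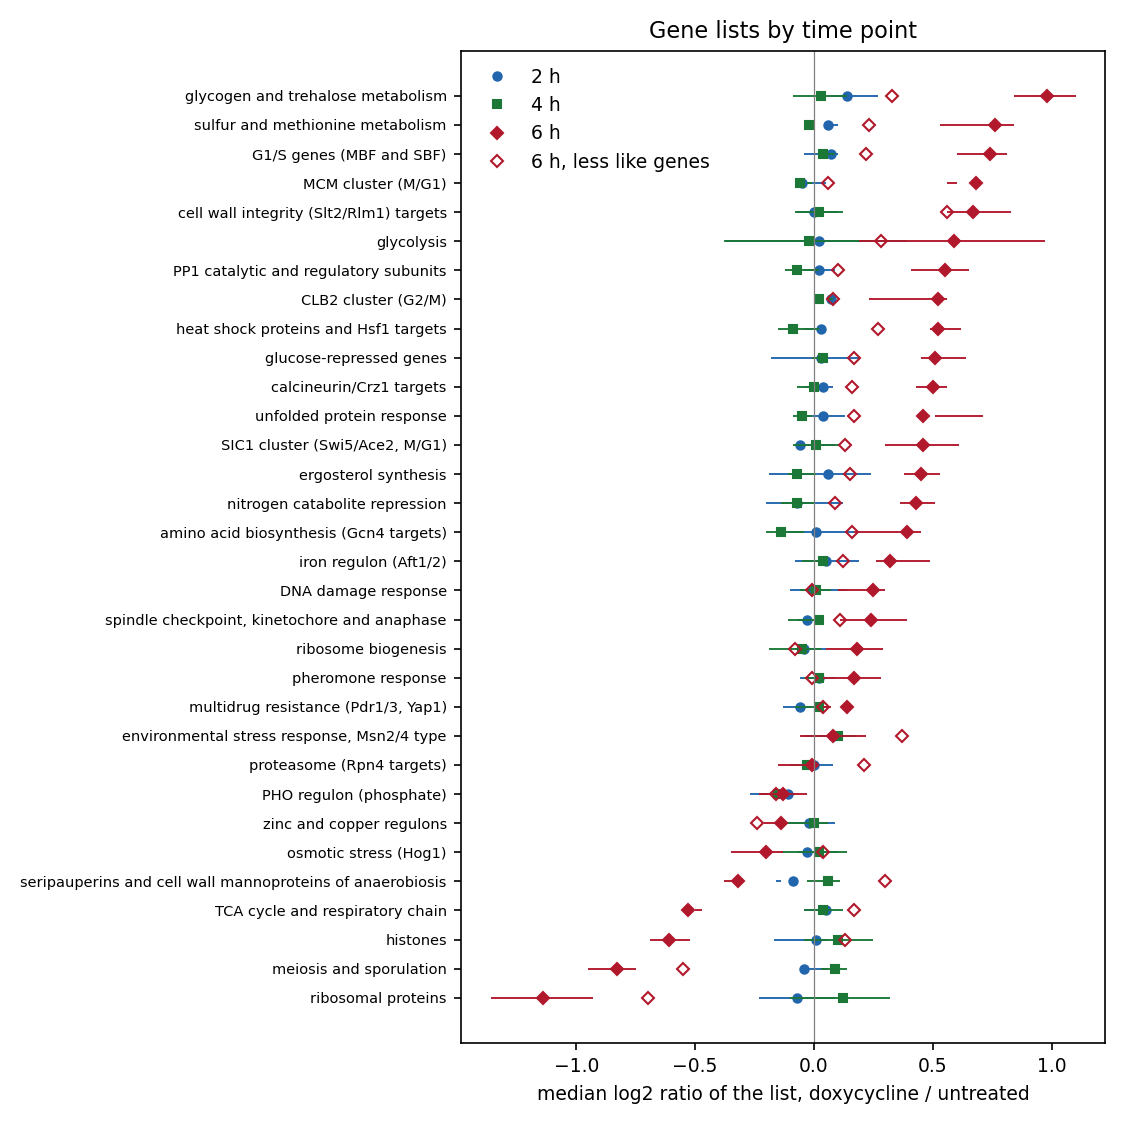
Median log2 ratio of treated over untreated cells (horizontal axis) for each gene list (vertical axis) at 2, 4 and 6 h, where points are medians of the means of 2 arrays, bars span the 2 array medians, which need not enclose the point, and open diamonds (less like genes) are 6 h medians relative to matched genes. Ribosomal protein genes lay at −1.14 and glycogen and trehalose genes at 0.98 at 6 h, and at −0.70 and 0.33 relative to matched genes.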

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

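All tests in this part but the run without 6 h were chosen after the results were seen, and the differences between times below were not tested.

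The 6 h ratios went with gene length and with the chromosome. The 20 genes nearest in length on the same chromosome took 53.8% of the variance of the 6 h mean, against at most 39.4% in 100 shuffles of the chromosomes, a difference of 14.3 that a smooth trend with length alone does not give. Ribosomal protein genes did not make the trend, since its Spearman correlation without them was 0.62, nor did the dye alone, since the lower of the 2 arrays still gave 0.58. Printed DNA grouped by length and chromosome is a candidate explanation, since the same difference was at least 7.1 on every one of the 6 arrays, though the array layout was not given in the sources used here. A difference in RNA or cDNA length between the samples cannot be told apart from the treatment with 1 RNA pair at 6 h, and an effect of YPI1 shut-off or of doxycycline stays open as untested.

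Ribosomal protein genes were low at 6 h, with a median of −1.14, and the list turned direction without 6 h (camera adjusted p = 0.208). The class of annotated gene length did not account for the whole. Among genes up to 522 bp the 22 ribosomal protein genes lay at −1.46 (SD 0.26). The 443 others lay at −0.80 (SD 0.42), a difference of −0.66. Grouping by annotated length and chromosome did not either, since the 120 ribosomal protein genes had a median of −0.70 relative to matched genes. These lengths include introns, and length was not matched within the class up to 522 bp. Neither comparison tests the length of the RNA or cDNA, which stays open for these genes. A bias of the brightest spots stays open, since signal was not analysed here and glycolysis genes, which such a bias would lower if their spots are as bright, lay at 0.39 from the length curve but at −0.06 and 0.63 on the 2 arrays relative to matched genes. A slower growth of cells without YPI1, an effect of doxycycline, or chance in the 1 RNA pair of 6 h all stay open as untested.

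CDC26 was low on all 6 arrays, as YPI1 was. A change shared by neighbouring genes was not seen at 2 h and 4 h. The lowest value then among measured genes beside YPI1 and CDC26 was −0.28, of NIC96. Beside CDC26, YFR035C had 0.06 at 2 h and no pair of values at 4 h. RSC8 had −0.12 at 4 h and no pair of values at 2 h. At 6 h YFR035C was at −0.90 and RSC8 at 1.23. YPI1 cDNA on the CDC26 spot stays open as an explanation. A spot whose own share is 23.1%, solved from 2 h, gives −2.01 at 4 h, which CDC26 missed by −0.09, within its SD of 0.22. A ratio unchanged from the 2 h value of −1.90 would also lie within that SD of the 4 h value of −2.09. The match at 4 h therefore does not favour a summed spot. The same spot gives −2.05 at 6 h, which CDC26 missed by −0.96, or −2.81 if its own share moves with short genes, so the explanation cannot be told apart from a real fall of CDC26. The criterion for this test was made stricter after its 4 h value was seen, and a change of CDC26 after YPI1 shut-off stays open.

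Of the 4 sign flips of the 3 times, 1 gave as many genes as the test of the mean (real count 1, highest other 0) and 1 as many as the slope test (real count 2, highest other 0), and 4 are too few for a share under 0.05.

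The arrays of 6 h were all above 0 and those of 4 h all below, or the reverse, for the following, given as the 6 h mean less the 4 h mean. Genes and differences were RPL29 −2.04, PAU23 −1.34, NOP12 2.88, YAR010C 2.65, YJR028W 2.60, YFL032W 2.51, DSS1 2.42, NCP1 2.39, ADE57 2.31, LYS4 2.28, TRP5 2.19, GLN3 2.14, SCD5 2.07, STI1 2.03, CDC48 1.89, PMT2 1.83, NDI1 1.73, PFK2 1.71, PMT1 1.71, PMR1 1.66, PPZ2 1.5, ALK1 1.40, CHS2 1.34, VTC3 1.32, RAD52 0.99, NIC96 0.48 and GLC7 0.22. Among lists the meiosis list gave −0.93, the unfolded protein response 0.66, the MCM cluster 0.60 and amino acid biosynthesis 0.43, each as a difference of the means of the array medians.

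Between 6 h and 2 h the arrays parted in the same way for DAK2 (−1.91), DSE2 (1.45), VTC3 (0.92) and the multidrug resistance list (0.12). Between 4 h and 2 h they parted for ALK1 (−0.55), CHS2 (−0.47), CDC48 (−0.47), SCD5 (−0.31), RAD52 (−0.30), GLC7 (−0.28), DSE2 (0.35) and the proteasome list (−0.10).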

How the results depend on the processing

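The choice not to make the sign turn, and both length corrections with their values, came after seeing the data. The direction of YPI1 held under every alternative but the sign turn, which put it at 0.34 at 2 h and 0.16 at 4 h, by construction. The mean test (1 gene) called 8 after scaling, 2 with 6 arrays and no block, with the replicate block, the dye term or a random block for time, 2 with the length curve removed, and 0 with the sign turn or relative to matched genes. Left-out arrays or times gave 1 to 11, with 11 without 6 h and 2 without 2 h or without 4 h. The slope test (2 genes) called 4 after scaling, 3 with 6 arrays and no block, 2 with the replicate block, and 0 with the sign turn, the length curve removed or relative to matched genes. Left-out arrays or times gave 2 to 1768, with 1768 without 4 h and 11 without 6 h. Relative to matched genes YPI1 kept its size (mean −5.39, SE 0.35, and −5.24, SE 0.32), and its call ended with the prior degrees of freedom, 4.37 before and 2.58 after. At 2 h (2 genes) left-out arrays gave 17 to 29. At 4 h (3 genes) scaling gave 5, 1.5-fold 5, left-out arrays 4 to 5 and the sign turn 1. At 6 h (459 genes) scaling gave 2, 1.5-fold 1554, 3-fold 35, the mean of both arrays 745, left-out arrays 827 to 966, the length curve 233 and matched genes 135. For lists (11 called) an estimated correlation and fry gave 0, with lowest adjusted p of 0.662 and 0.676, and left-out arrays or times 4 to 12, with 4 without replicate 1, 11 without replicate 2, 12 without 2 h, 8 without 4 h and 6 without 6 h. Over left-out arrays and times, camera adjusted p ran from 0.00937 to 0.975 for ergosterol, 5.97e-05 to 0.878 for glycolysis, 0.00801 to 0.71 for meiosis and 6.47e-24 to 0.208 for ribosomal proteins, the higher value without 6 h and reversed. ALK1 at 6 h turned to −0.07 relative to matched genes. Except as given, the cause was not tested. The deviations of same-numbered arrays correlated between times with r = 0.57, −0.71 and −0.54, with signs that follow the dye orientation. They cannot show whether the experiment numbers pair the arrays. The replicate block changed no other call. For named genes 367 values moved by more than their spread, 1697 did not, 3 reversed, 20 newly passed and 7 no longer passed, and for lists 113 moved, 458 did not, 4 reversed and 48 no longer passed. The list counts hold no class for newly called lists, though camera called 4 more relative to matched genes, 3 of them turned in direction. Lists outside the 11 called also turned under other alternatives, so 4 is not a count of every list that turned. Signal over background was not analysed here, so its limit is unknown.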

Other observations

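The tests relative to matched genes and the tests of the swapped arrays were chosen after the results were seen, and the runs without 6 h were not. The prediction for weak spots was written beforehand, but its test used the length curve, which was added after the values were seen.

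Before 6 h, some phosphate genes stood out beyond YPI1 and CDC26. With 6 h left out, limma called 11 genes, on 1 residual degree of freedom and a spread shared by all genes (SE 0.11). Among them the acid phosphatases PHO12 (mean −0.62, adjusted p = 5.1e-06) and PHO11 (−0.50, adjusted p = 0.0012) and the polyphosphate gene VTC3 (−0.58, adjusted p = 3.9e-05) were lower on all 4 arrays, and the PHO list was down (camera adjusted p = 1.87e-06). The limma p of a gene in this run rests on the shared spread and does not measure its own. Over the 2 arrays the SDs at 2 h and 4 h were 0.29 and 0.40 for PHO12. They were 0.50 and 0.19 for PHO11, and 0.15 and 0.07 for VTC3. An estimated correlation was not run without 6 h, and over all times the PHO list had adjusted p = 0.662 with an estimated correlation. The list of Glc7 regulators passed there too (camera adjusted p = 5.3e-23), but it holds YPI1, the gene shut off by design, and its medians at 2 h and 4 h were 0.02 and −0.07, so that call says nothing of its other members. At 6 h VTC3 was above 0 at 0.54 and PHO11 at 0.02, but relative to matched genes they were at −0.47 and −0.67. PHO11 and PHO12 are near-identical copies and cannot be separated by cDNA on such arrays.

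SNZ1, of vitamin B6 synthesis, was also lower on the 4 arrays (limma mean −0.58, adjusted p = 3.5e-05), as were PAU11 (−0.57, adjusted p = 4.9e-05), carbonic anhydrase NCE103 (−0.50, adjusted p = 0.0012) and BOP2 (−0.41, adjusted p = 0.035). The membrane stress protein HSP30 (0.44, adjusted p = 0.012) and the weak-acid pump PDR12 (0.42, adjusted p = 0.028) were higher. At 6 h SNZ1 lay at −0.44 (0.02 relative to matched genes), PAU11 at −0.74 (−0.02), NCE103 at −0.59 (−0.12), HSP30 at 0.40 (0.40) and PDR12 at 1.19 (0.69), and BOP2 had no value. Amino acid biosynthesis genes were down as a list without 6 h (camera adjusted p = 0.0357) but up without 4 h (0.0304) and up over all times without passing (0.153). Over all times this list had adjusted p = 0.718 with an estimated correlation.

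Relative to matched genes, camera called 4 lists that it did not call on the uncorrected values of all 3 times. The PHO regulon (adjusted p = 0.000487) and ribosome biogenesis (adjusted p = 0.00825) were down, and histones (adjusted p = 0.024) and TCA cycle and respiratory genes (adjusted p = 0.0271) were up. On the uncorrected values ribosome biogenesis ran up (adjusted p = 0.797) and histones (0.393) and TCA cycle genes (0.61) down, so the correction turned 3 of the 4. An estimated correlation was not run on these values.

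The swapped arrays of 2 h and 4 h correlated below 0 across genes, as a dye bias of single genes would give. The deviation of a gene from the mean of its swapped arrays, turned by dye, correlated between times with r of at least 0.54, which is consistent with such a bias. Arrays left unturned by the authors would put YPI1 above 0 on some arrays, but its highest value was −4.06.

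Weak spots that read low at 6 h were considered for the low meiosis list. The 684 genes missing on an earlier array lay 0.09 above the 3235 genes present on all 4 of them, less the length curve, against −0.05 to 0.05 in random draws. This leaves open how weak spots act on the meiosis list, since genes had to pass the spot filter at 6 h to be counted and only 1 of the 10 measured members was missing on an earlier array.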
